A study of Arabidopsis thaliana with 16 samples.

How the data were processed

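RNA sequencing of Arabidopsis thaliana was analysed in 16 libraries, which formed 8 groups of 2 replicates. In 1 table, 2-week seedlings were wild type (WT), ddm1, tcx5/6 or tcx5/6 ddm1. The other table held leaf and shoot apical meristem (SAM) libraries from WT and tcx5/6 plants. The labels gave growth on MS plates at 22 °C with 16 h light and 8 h dark, and leaf at 1 month. The tissue field of the labels reads seedlings for leaf and SAM libraries as well, so tissue was taken from the titles. Nothing in the labels states that replicates were separate cultures, so p-values measure only the spread between the samples sequenced.

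The deposited values have the unit signal: read counts per gene that the authors adjusted to a common library size, so that whole-number steps became fractions. They are not raw counts, not CPM and not divided by gene length. Per the labels, HISAT2, edgeR and the build TAIR10 were used. Their versions, the counting tool, the annotation used for counting and the strand setting are not given in the sources used here. Totals were 31.13 to 38.82 M per seedling library and 45.35 to 59.33 M per leaf or SAM library. Because the authors adjusted these totals, they are not the depth sequenced, which is not given here, and no counting intervals were computed. The spacing of the lowest values implied 23.3 to 29.5 M reads per library in WT and tcx5/6 seedlings. In ddm1 and tcx5/6 ddm1 seedlings it implied 41 to 51.6 M. These estimates take each step as 1 read, which was not checked. Replicates correlated at a Pearson r of 0.9841 to 0.9967 across genes with a group mean of at least 100 signal, where the median absolute log2 difference between replicates was 0.0618 to 0.158. Values below 1e-6 were read as 0.

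Each table was fitted by itself with limma 3.58.1 in R 4.3.3. The limma-trend method was applied to log2(value + 1) for genes with a value of at least 1 in at least 2 libraries, with 1 coefficient per group and all 8 libraries of the table in the fit. This tested 25016 genes in seedlings and 24429 in leaf and SAM. All log2 changes are on this scale, with a pseudocount of 1. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Figures and annotation classes were made with Python 3.11.15 and matplotlib 3.10.9. The tests, thresholds, gene lists and rules for naming genes were fixed before the data were examined. The count-based tests first foreseen (edgeR quasi-likelihood, with DESeq2 as alternative) were not run because the values are not counts. The limma-trend test had been set down for that case.

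Comparisons were tcx5/6 with WT in seedlings, leaf and SAM, ddm1 with WT, tcx5/6 ddm1 with WT and with ddm1, WT SAM with WT leaf, and 2 interactions. The first interaction asked whether the tcx5/6 difference depended on ddm1, and the other whether it differed between SAM and leaf. The fixed material held 22 lists: TCX family, DREAM subunits and E2F, DNA methylation maintenance, RNA-directed DNA methylation, active DNA demethylation, DNA replication, G2/M cell cycle, G1 cyclins and CDK inhibitors, DNA damage response, meiosis, replication-coupled histones, methylation-silenced genes, photosynthesis, shoot meristem, floral organ, root, and seed storage markers, salicylic acid defence, heat shock, circadian clock, anthocyanin synthesis and transposon-related genes. Transposon-related genes were 220 loci whose product or note in the TAIR10.1 annotation names a transposon protein. This class holds host genes too, and whether it covers all transposable element genes was not checked. The list of replication-coupled histones held histone H3.1 and H2A.W genes. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, then with an estimated correlation and with fry. Members called were also counted with p-values adjusted over the list alone. Overlaps of called genes were tested with Fisher's exact test, one-sided, between pairs of comparisons that share no library.

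Genes were named by rule. TCX5, TCX6 and DDM1 came first. Then came up to 6 genes with the largest rise and 6 with the largest fall among called genes with a symbol, no overlap of libraries between groups and a mean of at least 5 CPM (3 per direction for interactions and for WT SAM with WT leaf). Then followed up to 3 members per list with the smallest p-values among those called, or the 1 member with the smallest p-value where none was called. Other list members are named where a group is described.

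Alternatives tried were rescaling by the median of ratios, no filter on low values, a pseudocount of 0.1, a minimum absolute log2 change of 1, a fit on the compared groups alone, the replicate number as a block, and leaving out each library. A filter at a value of at least 20 was added after seeing the data. The pipeline was tested on simulated data with 200 changed genes. In the simulated seedling comparison 16.7% of 1.5-fold changes, 60% of 2-fold changes and 75.4% of 4-fold changes were recovered, with 4 false calls. In the simulated leaf comparison these shares were 50.8%, 77.3% and 94.5% (31, 51 and 69 genes), with 14 false calls. The simulation gave a gene the same normal noise in every group and changed few genes. It therefore does not give the error rates of the real comparisons, where spread differed between groups and many genes were called. All columns of both tables were used.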

Results

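RNA was measured in 16 libraries from Arabidopsis thaliana, in 8 groups of 2. Seedlings contributed 8 libraries, from WT, tcx5/6, ddm1 and tcx5/6 ddm1 plants. Leaf and SAM contributed the other 8, from WT and tcx5/6 plants. TCX5 and TCX6 are CXC-domain proteins of the DREAM complex, which represses cell cycle genes, and DDM1 is a chromatin remodeller needed to keep DNA methylated. Values are in deposited signal, given as mean ± SD with n = 2 unless stated, and log2 changes are differences of log2(value + 1) from limma-trend with Benjamini-Hochberg adjusted p. Total signal was 31.13 to 34.03 M in the seedling WT and tcx5/6 libraries, 31.6 to 38.82 M in the ddm1 and tcx5/6 ddm1 libraries, and 45.35 to 59.33 M in leaf and SAM. The seedling libraries also fell into 2 kinds. The share of low values on even steps was 26.5% to 31.3% in WT and tcx5/6 seedlings and 71.6% to 78.6% in ddm1 and tcx5/6 ddm1 seedlings. Every ddm1 or tcx5/6 ddm1 comparison with WT seedlings therefore also compared the 2 kinds, and the kind and the loss of DDM1 cannot be told apart. How reads shared between close paralogs, such as VIM2 and VIM4 or the CAB genes, were counted is not given in the sources used here, so their values are not known to be specific to each gene.

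The mutated genes came first. In libraries labelled tcx5/6, TCX5 was lower and TCX6 higher than in the matching group in every tissue and background. TCX5 (AT4G29000, TAIR10.1 chromosome 4, 14293513 to 14297066) read 253.8 ± 19.3 in tcx5/6 and 491.4 ± 7.55 in WT seedlings (log2 -0.95, adjusted p = 0.012). It read 480.9 ± 24.4 against 1138 ± 98.7 in leaf (log2 -1.24) and 521.1 ± 44.4 against 980.5 ± 11.7 in SAM (log2 -0.91). TCX6 (AT2G20110, chromosome 2, 8683979 to 8687283) read 771.2 ± 16.3 against 157.4 ± 7.41 in seedlings (log2 2.29, adjusted p = 0.00018), 1132 ± 177 against 291.6 ± 57.4 in leaf (log2 1.96) and 1860 ± 14.9 against 454.1 ± 89.1 in SAM (log2 2.05). In tcx5/6 ddm1 seedlings TCX5 read 211.9 ± 54.2 and TCX6 782.5 ± 72.6, against 630 ± 76.3 and 120.2 ± 32.3 in ddm1. TCX6 rose although the label names it as mutated. A transcript level does not tell whether the gene is intact, and values per exon were not used here. DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191) read 132 ± 18.7 in ddm1, 678.6 ± 43.4 in WT, 1993 ± 96 in tcx5/6 and 611.6 ± 60.6 in tcx5/6 ddm1 seedlings. The seedling call of TCX5 was lost when any single library of the pair was left out (adjusted p = 0.077 and 0.1 without WT replicate 1 or 2, 0.11 and 0.059 without tcx5/6 replicate 1 or 2).

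**Figure D1:**
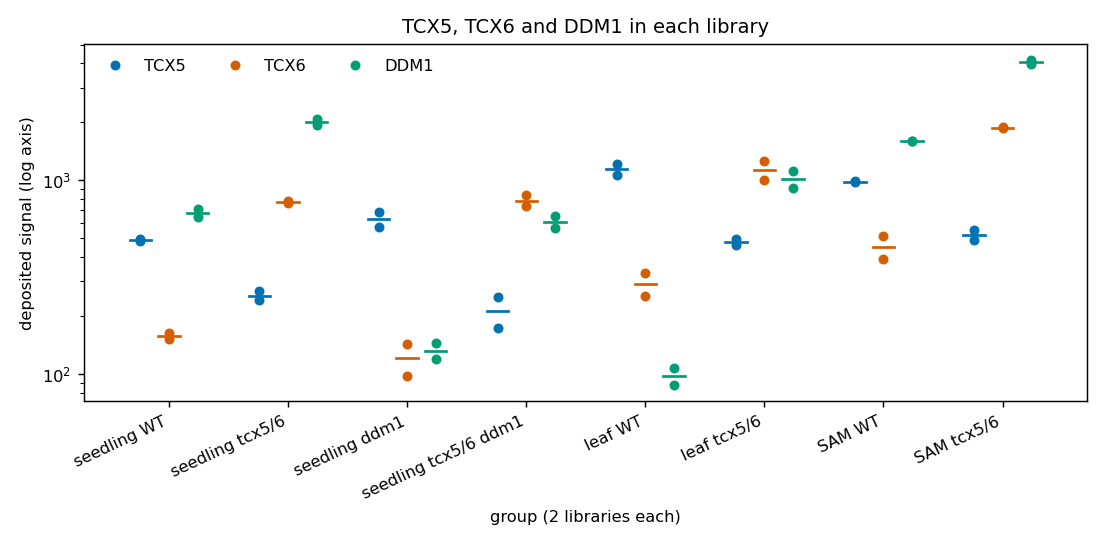
Deposited signal of TCX5, TCX6 and DDM1 on a log axis for the 8 groups, with a point for each library and a bar for the mean of 2. TCX6 lay between 731.1 and 1870 in the 8 libraries labelled tcx5/6 and between 97.35 and 517.1 in the others.

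The comparison of tcx5/6 with WT seedlings asked which transcripts differ in plants labelled tcx5/6. TIL2, which encodes a catalytic subunit of DNA polymerase epsilon, rose from 3.251 ± 1.9 to 1332 ± 20.5 (log2 8.37, adjusted p = 2.9e-05). The histone deacetylase gene HDA18 rose by log2 5.34, the methylated-DNA reader VIM4 by 5.11, the phosphatase gene BSU1 by 5.54, the meiotic gene AtSPO22 by 4.47 and the defensin PDF1.2 by 4.26. QQS, a regulator of starch content, was listed at 0 in both tcx5/6 libraries and at 1021 and 1031 in WT. ESM1, which shapes glucosinolate breakdown, fell from 20300 ± 286 to 1070 ± 9.04 (log2 -4.24, adjusted p = 3.3e-06). Other large falls were in the SUMO-activating enzyme gene SAE1B (log2 -5.23), the iron-response regulators BHLH100 (log2 -3.44) and bHLH39 (log2 -2.63), and the methionine aminopeptidase gene MAP1B (log2 -2.14).

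In DNA methylation maintenance, 9 of 12 genes rose and 3 did not pass (10 rose adjusted over the list alone), with a camera adjusted p of 2.3e-12. CMT3, the CHG methyltransferase, rose from 1229 ± 98.3 to 4834 ± 122, DDM1 rose by log2 1.55, and VIM2 and the histone methyltransferase gene SUVH4 by 2.83 and 1.28. CMT2 (log2 0.03) and SUVH6 (log2 -0.03) did not pass. Of 27 DNA replication genes 23 rose and 4 did not pass (25 over the list alone, camera adjusted p = 2.1e-19), among them FAS1 (log2 1.67), POL2A (1.30) and POLD1 (1.26). All 14 meiosis genes rose, both over all genes and adjusted over the list alone (camera adjusted p = 1.2e-15), and those with the smallest p-values were the axis gene ASY1 (log2 4.17), the crossover gene SHOC1 (4.04) and the recombinase gene DMC1 (2.75). In the DNA damage response 10 of 12 rose and 2 did not pass (11 over the list alone, camera adjusted p = 1.6e-11), with NAC044 at log2 3.58 and PARP2 at 1.64. Of the DREAM subunits and E2F factors 14 of 17 rose and 3 did not pass (16 over the list alone, camera adjusted p = 2.9e-15), with ALY1 at log2 2.81, DEL3 at 2.37 and E2FC at 1.72. In the TCX family 5 of 8 rose, 1 (TCX5) fell and 2 did not pass (7 and 1 over the list alone, camera adjusted p = 1.6e-05), with TCX4 at log2 1.96 and TCX3 at 1.13. The 5 include TCX6, so both labelled genes count in this list.

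Of 32 G2/M genes 13 rose and 19 did not pass (17 over the list alone), including AUR3 (log2 2.15), CDKB1;1 (1.49) and TES (1.18). Camera gave an adjusted p of 5.1e-13, and adjusted p = 0.146 with an estimated correlation. In the replication-coupled histone H3.1 and H2A.W list 6 of 8 genes rose and 2 did not pass, as over the list alone, with HTR2 at log2 0.62. For this list camera gave an adjusted p of 0.00044, and adjusted p = 0.233 with an estimated correlation. Among methylation-silenced genes, which lose expression when methylated, QQS and SDC fell and 2 of 4 did not pass, as over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.113 with an estimated correlation). SDC was listed at 0 in tcx5/6 and at 4.649 and 3.33 in WT, and lost its call without WT replicate 1 (adjusted p = 0.05). None of 10 photosynthesis genes passed, over all genes or the list alone, and their log2 changes lay between -0.50 and -0.22 (camera adjusted p = 0.0037, and adjusted p = 0.593 with an estimated correlation). RNA-directed DNA methylation had 5 of 22 genes higher, among them AGO6 (log2 2.29) and RDR2 (1.24), and active demethylation 2 of 9, led by ZDP (1.15), with camera adjusted p of 0.13 and 0.41. G1 cyclins and CDK inhibitors (adjusted p = 0.66) had 1 gene higher, SMR4 (log2 3.75), and 1 lower, CYCD3;2 (-0.43), whose call was lost without WT replicate 1 or 2 (adjusted p = 0.22 and 0.21) or tcx5/6 replicate 1 or 2 (0.28 and 0.15). Shoot meristem (0.72), floral organ (0.66), root (0.091), seed storage (0.94), salicylic acid defence (0.52), heat shock (0.92), circadian clock (0.66) and anthocyanin (0.12) lists were not called by camera. Within them the called genes were SEP3 (log2 1.42), the phosphate exporter gene PHO1 (0.41), SAG101 (0.49), HSP90.1 (0.75) and LUX (0.42), which rose, and the clock gene PRR9 (-0.68), which fell. Calls were lost without WT replicate 1 in SAG101, HSP90.1 and LUX (adjusted p = 0.086, 0.096 and 0.054) and without WT replicate 2 in these and PRR9 (0.11, 0.098, 0.1 and 0.1). They were also lost in these 4 genes, in the same order, without tcx5/6 replicate 1 (0.061, 0.13, 0.087 and 0.067) and without tcx5/6 replicate 2 (0.14, 0.054, 0.085 and 0.08). The seed storage list had a median log2 change of 0.03 and a mean of 0.19 while camera pointed down. Of 103 transposon-related genes 8 rose, 1 fell and 94 did not pass (camera adjusted p = 0.63). AT1G49920 rose by log2 4.70 and FRS2, which encodes a domesticated transposase that acts as a transcription factor, by 0.81.

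Of 25016 genes 2905 were called, 1816 higher and 1089 lower. Of these 943 changed at least 2-fold, 798 higher and 145 lower. Without WT replicate 1 or 2 the count was 1313 (966 higher, 347 lower) or 1016 (838 and 178), and without tcx5/6 replicate 1 or 2 it was 988 (795 and 193) or 1099 (807 and 292). A fit on the 4 compared libraries alone called 6508 (3532 and 2976).

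**Figure D2:**
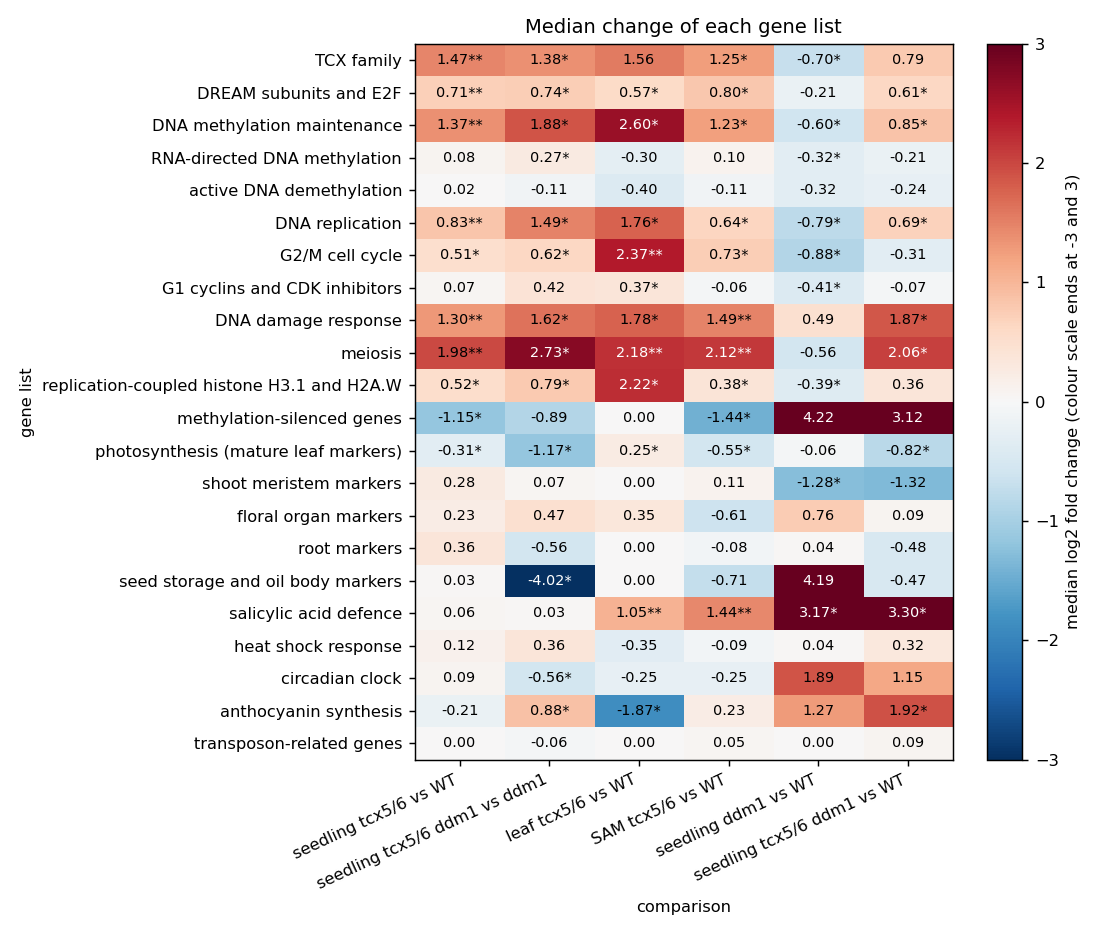
Median log2 change of each gene list (vertical axis) in 6 comparisons (horizontal axis), with colour and number giving the median. Lists with 1 star passed camera at the preset correlation and those with 2 stars also with an estimated correlation, where the DNA methylation maintenance median was 1.37 in tcx5/6 seedlings.

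The comparison of ddm1 with WT seedlings asked what follows the loss of DDM1 alone, with the difference in library kind described above. SDC, an F-box gene silenced by methylation, rose from 3.99 ± 0.932 to 5214 ± 1350 (log2 10.02, adjusted p = 6.3e-07). FWA, a methylation-silenced homeobox gene, was listed at 0 in WT and at 147.8 and 252.2 in ddm1. The loci annotated as MIR854a, MIR854b and MIR854c were listed at 0 in WT and lay between 685.4 and 1102 in ddm1. Their values are not known to be specific to each locus either. The phosphatase gene PAP5 rose by log2 8.82 and OFP9 by 8.76. Among 103 transposon-related genes 33 rose, 19 fell and 51 did not pass (33 and 21 over the list alone), with a median of 0.00, a mean of 1.69 and a camera adjusted p of 0.26. AT3G43837, AT3G30820 and AT3G42723 were listed at 0 in WT and at 1401 and 1263, 781.7 and 787, and 637.9 and 720.9 in ddm1.

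Salicylic acid defence genes rose in 12 of 13 cases and 1 did not pass, as over the list alone (camera adjusted p = 1.8e-07, and adjusted p = 0.286 with an estimated correlation). PR1 rose from 447.6 ± 74.8 to 40480 ± 12800, PR2 from 258.2 ± 5.7 to 4140 ± 25.9, and SAG101 by log2 2.28. Replication genes fell in 26 of 27 cases (27 over the list alone), among them POLD1 (log2 -0.88) and MCM3 (-0.95), with a camera adjusted p of 4.9e-09 and adjusted p = 0.245 with an estimated correlation. G2/M genes fell in 29 of 32 cases and 3 did not pass, as over the list alone, with the syntaxin gene KN at log2 -1.29 (camera adjusted p = 3.1e-09, and adjusted p = 0.286 with an estimated correlation). Of 11 shoot meristem markers KNAT1 (log2 -2.54), ANT (-1.28) and KNAT6 (-0.96) fell and 8 did not pass, among them FD (0.81), as over the list alone (camera adjusted p = 0.042, and adjusted p = 0.504 with an estimated correlation). STM read 49.68 ± 18.9 against 134 ± 18.4 (log2 -1.46, adjusted p = 0.066). A smaller share of meristem tissue in the ddm1 libraries was not tested. In DNA methylation maintenance 8 of 12 genes fell, as over the list alone, with CMT3 at log2 -0.94 (camera adjusted p = 0.0028, and adjusted p = 0.245 with an estimated correlation). This list and the 8 include DDM1 itself (log2 -2.36). RNA-directed DNA methylation had 11 of 22 genes lower and 2 higher, as over the list alone, with SUVH9 at log2 -2.82 and NRPE1 at -1.63 (camera adjusted p = 0.0047, and adjusted p = 0.245 with an estimated correlation). The demethylase gene ROS1 fell by 1.76 on the log2 scale. The remaining large falls were in PRB1 (log2 -5.76), ASG4 (-4.80), the clock gene LHY (-4.71), SAE1B (-4.59), the arginase gene ARGAH2 (-4.36) and STR16 (-4.12). STR16 lost its call without WT replicate 1, WT replicate 2 or ddm1 replicate 1 (adjusted p = 0.06, 0.06 and 0.081).

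Clock genes moved in opposite directions by their time of expression. All 13 were called, 8 higher and 5 lower, as over the list alone (camera adjusted p = 0.22). The morning genes CCA1 (log2 -3.01), LHY and RVE8 (-3.37) fell, and the evening genes LUX (3.59), ELF4 (5.12), GI (2.00) and TOC1 (2.69) rose. For these morning and evening genes the same split between the 2 kinds of seedling libraries held in tcx5/6 ddm1. CCA1 read 6975 and 7577 in WT, 5215 and 5519 in tcx5/6, 802.3 and 1016 in ddm1, and 476.7 and 248.9 in tcx5/6 ddm1. Seed storage transcripts stood apart in ddm1 replicate 1. CRC (AT4G28520, cruciferin) read 854.4 there and 5.093 in replicate 2, and CRA1 630.3 and 20.14. Of 8 seed storage genes 3 rose and 5 did not pass (2 over the list alone, camera adjusted p = 0.095). CRC lost its call without WT replicate 1 or 2 or ddm1 replicate 1 (adjusted p = 0.1, 0.2 and 0.19). Of 25016 genes 12418 were called, 6584 higher and 5834 lower, with 5376 at least 2-fold (3260 higher, 2116 lower).

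**Figure D3:**
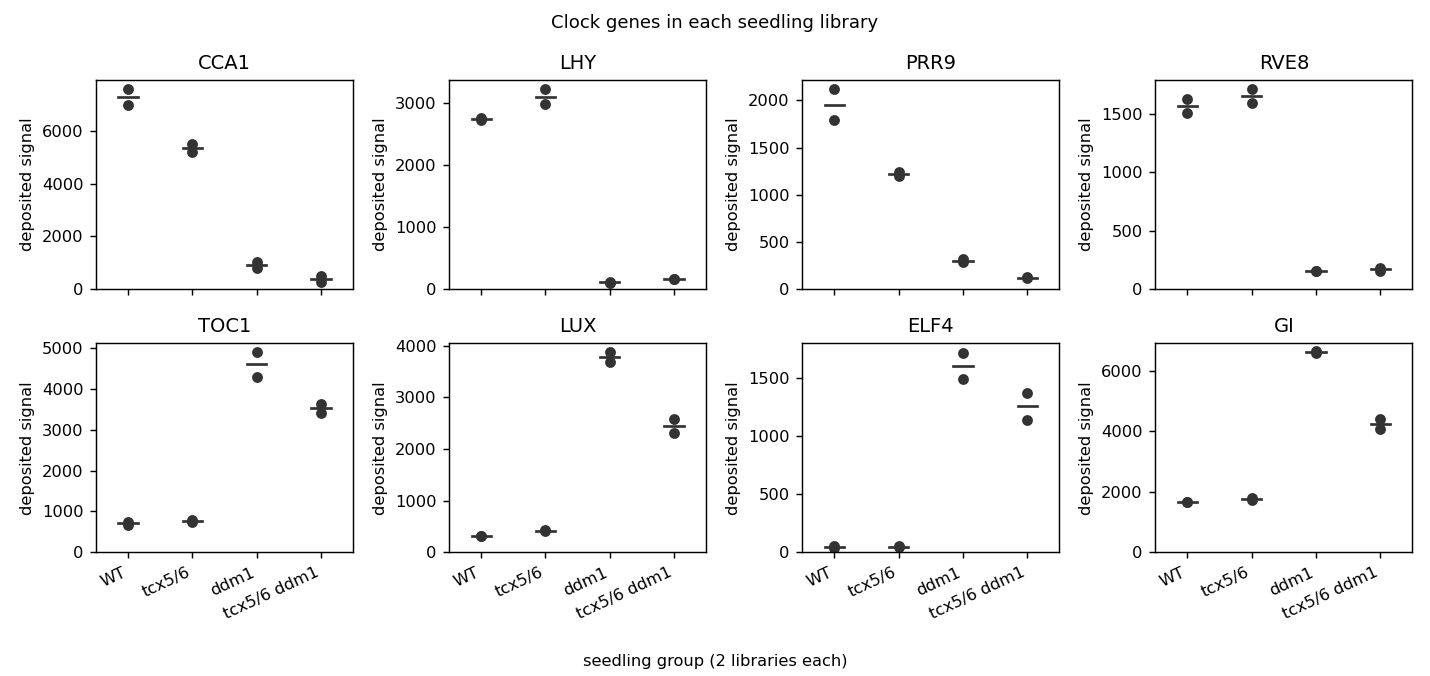
Deposited signal of 8 clock genes in the 4 seedling groups, with a point for each library and a bar for the mean of 2. CCA1 lay between 5215 and 7577 in WT and tcx5/6 and between 248.9 and 1016 in ddm1 and tcx5/6 ddm1.

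In tcx5/6 ddm1 against WT seedlings, the question was which transcripts differ in plants labelled for all 3 genes. TCX6 read higher, at 782.5 ± 72.6 against 157.4 ± 7.41 (log2 2.30). DDM1 read 611.6 ± 60.6 against 678.6 ± 43.4 (log2 -0.15, adjusted p = 0.34). A transcript level does not tell whether either gene is intact. DDM1 also rose in tcx5/6 against WT seedlings (log2 1.55). The transposon-related genes with the smallest p-values, AT3G43837, AT3G42723 and AT1G36085, were listed at 0 in WT. They averaged 1040, 465.7 and 641.8 in tcx5/6 ddm1. DXPS1, which encodes an enzyme of the plastid isoprenoid pathway family, rose by log2 9.18, the aldehyde oxidase gene AO4 by 9.13, the defensin PDF1.2b by 8.89, the beta-amylase gene BAM5 by 8.75 and CSLG2 by 8.71. ADPG1, a polygalacturonase gene, was listed at 0 in WT and at 453.5 and 567.8 in tcx5/6 ddm1. Falls were largest in BGLU7 (log2 -7.20), TPS12 (-6.99), FADA (-5.79), NIG1 (-5.38), SAE1B (-5.19) and the carotene hydroxylase gene BETA-OHASE 2 (-4.98). SDC rose by log2 5.19, and PR1 rose to 105000 ± 34500. Meiosis genes rose in 13 of 14 cases, as over the list alone, with ASY1 at log2 6.18 (camera adjusted p = 5.9e-05, and adjusted p = 0.411 with an estimated correlation). DNA damage genes rose in 10 of 12 cases and 1 fell, as over the list alone (camera adjusted p = 0.00038, and adjusted p = 0.311 with an estimated correlation). Replication genes rose in 18 of 27 cases and 2 fell, as over the list alone (camera adjusted p = 0.00038, and adjusted p = 0.411 with an estimated correlation), with the ribonucleotide reductase gene TSO2 at log2 2.06. Salicylic acid defence genes rose in 12 of 13 cases and anthocyanin genes in 9 of 9, as over the lists alone (camera adjusted p = 6.6e-06 and 0.0017), with adjusted p = 0.411 and adjusted p = 0.515 with an estimated correlation. Photosynthesis genes fell in 9 of 10 cases, as over the list alone, with RCA at log2 -2.33 (camera adjusted p = 0.00083, and adjusted p = 0.564 with an estimated correlation). Of 25016 genes 13969 were called, 7372 higher and 6597 lower, with 6650 at least 2-fold (3803 higher, 2847 lower). The difference in library kind applies here too.

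In tcx5/6 ddm1 against ddm1, 2 groups of the same library kind, the question was whether the tcx5/6 difference also appears in plants labelled ddm1. DDM1 itself was not equal in the 2 groups. It read 611.6 ± 60.6 in tcx5/6 ddm1, near the 678.6 ± 43.4 of WT, and 132 ± 18.7 in ddm1 (log2 2.21, adjusted p = 1.7e-05). ADPG1 rose by log2 7.77, AtSPO22 by 5.91, the succinate dehydrogenase gene SDH1-2 by 5.41, VIM4 by 5.40, HDA18 by 5.31 and BSU1 by 5.01. SDC fell by 4.82 on the log2 scale, from 5214 ± 1350 to 187.8 ± 76.3. The light-signalling gene PAR1 (log2 -4.17), the chlorophyll synthesis gene PORA (-3.89) and the marneral synthase gene MRN1 (-3.51) also fell. EPR1 (AT2G27380) and CRC were listed at 0 in tcx5/6 ddm1. In ddm1 they read 935 and 24.99, and 854.4 and 5.093, so replicate 1 set their size, and CRC lost its call without it (adjusted p = 0.07) and without tcx5/6 ddm1 replicate 1 or 2 (0.1 in both). Replication genes rose in 27 of 27 cases, as over the list alone, with TSO2 at log2 2.58 (camera adjusted p = 3.1e-18, and adjusted p = 0.0724 with an estimated correlation). In DNA methylation maintenance 10 of 12 genes rose and CMT2 fell (log2 -0.60), as over the list alone, with CMT3 at log2 2.39 and VIM2 at 3.80 (camera adjusted p = 2.9e-07, and adjusted p = 0.0547 with an estimated correlation). The 10 include DDM1. Meiosis genes rose in 13 of 14 cases and DNA damage genes in 11 of 12, as over the lists alone (camera adjusted p = 1.9e-10 and 2.9e-07), with adjusted p = 0.11 and adjusted p = 0.0547 with an estimated correlation. G2/M genes rose in 25 of 32 cases (27 over the list alone, camera adjusted p = 7.9e-11, and adjusted p = 0.163 with an estimated correlation). Photosynthesis genes fell in 8 of 10 cases, as over the list alone, with LHCB2.1 at log2 -1.35 (camera adjusted p = 0.00019, and adjusted p = 0.418 with an estimated correlation). In the transposon-related class 14 of 103 rose and 10 fell (12 and 8 over the list alone), with median and mean both -0.06 while camera pointed up (adjusted p = 0.91). Of 25016 genes 9832 were called, 4427 higher and 5405 lower, with 3513 at least 2-fold (1751 higher, 1762 lower), and a fit on the 4 compared libraries alone called 6497.

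**Figure D4:**
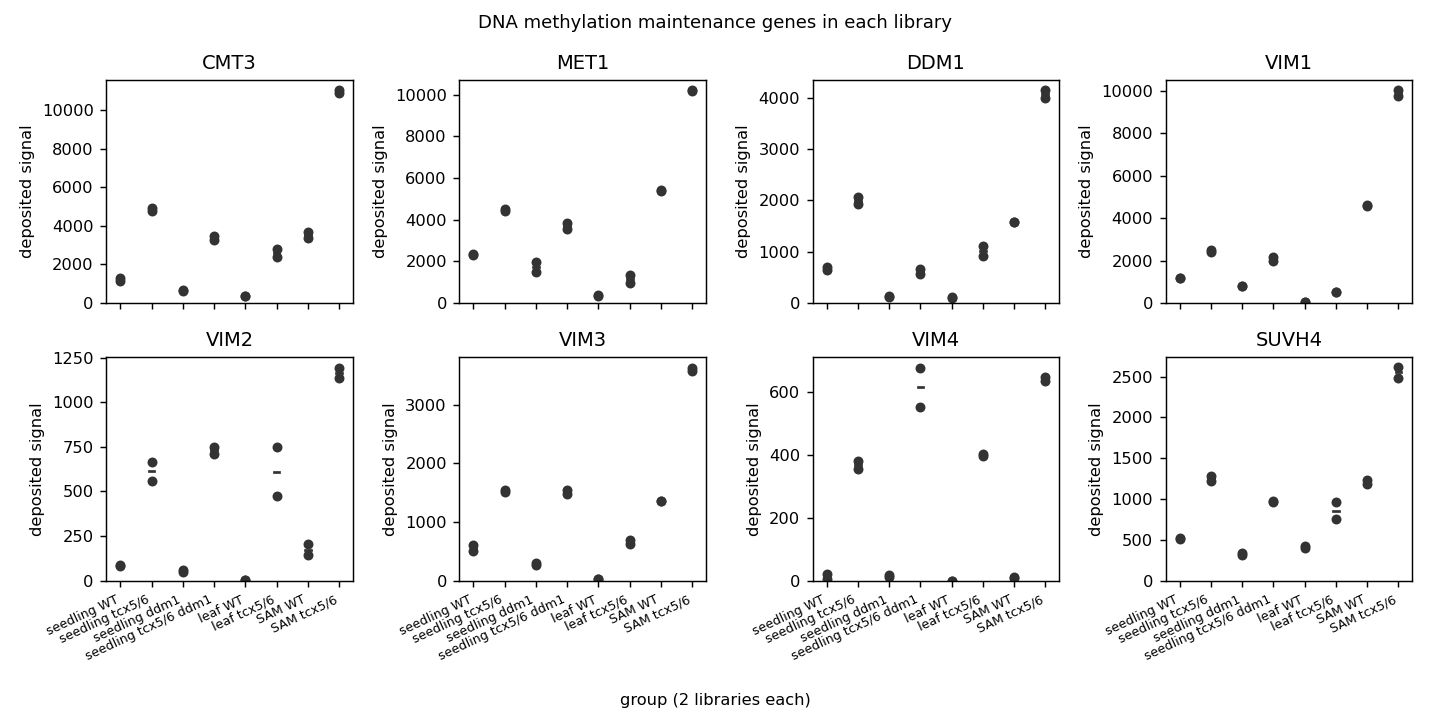
Deposited signal of 8 DNA methylation maintenance genes in the 8 groups on linear axes, with a point for each library and a bar for the mean of 2. CMT3 averaged 1229 in WT, 4834 in tcx5/6, 639.5 in ddm1 and 3361 in tcx5/6 ddm1 seedlings.

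The leaf comparison of tcx5/6 with WT asked what changes in a tissue where most cells have stopped dividing. The sucrose-phosphatase gene SPP1 rose from 1.063 ± 1.47 to 1616 ± 59.8 (log2 9.83, adjusted p = 1.6e-05). VIM2 rose by log2 6.81, the mitotic kinase gene CDKB1;1 by 6.80, BSU1 by 6.74, the spindle checkpoint gene BUB3.2 by 6.50 and HDA18 by 5.35. DDM1 rose from 97.69 ± 14.3 to 1015 ± 143, and VIM4 was listed at 0 in WT and at 404.2 and 397.7 in tcx5/6. QQS was listed at 0 in tcx5/6 and at 815.1 and 868 in WT. ESM1 fell by 6.84 on the log2 scale, MAP1B by 2.45 and the trehalose-phosphate synthase gene TPS5 by 2.09. CYP81D11 read 1009 ± 135 against 6001 ± 64.3 (log2 -2.58). It lost its call without WT replicate 1 or 2 (adjusted p = 0.14 in both), without tcx5/6 replicate 1 or 2 (0.11 and 0.13) and with a pseudocount of 0.1 (0.31).

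Replication genes rose in 27 of 27 cases in leaf, as over the list alone, with TSO2 at log2 3.12 and ORC1B at 3.72 (camera adjusted p = 3.3e-16, and adjusted p = 0.073 with an estimated correlation). G2/M genes rose in 28 of 32 cases (29 over the list alone, camera adjusted p = 1.9e-11), and meiosis genes in 11 of 14 (12 over the list alone, camera adjusted p = 6.7e-07), with DMC1 at log2 4.61. Salicylic acid defence genes rose in 13 of 13 cases, as over the list alone (camera adjusted p = 2.1e-08), with PR5 going from 17350 ± 198 to 198100 ± 7750 and PR2 from 66790 ± 579 to 320600 ± 3890. Methylation maintenance genes rose in 10 of 12 cases, as over the list alone, while CMT2 (log2 -1.45) and SUVH6 (-0.58) fell (camera adjusted p = 1.5e-05, and adjusted p = 0.107 with an estimated correlation). In the replication-coupled histone H3.1 and H2A.W list 7 of 8 genes rose and HTA12 fell, as over the list alone, with HTR13 at log2 3.07. For this list camera gave an adjusted p of 5.1e-06, and adjusted p = 0.107 with an estimated correlation. DNA damage genes rose in 9 of 12 cases and PARP1 fell (log2 -0.90), as over the list alone (camera adjusted p = 0.00021, and adjusted p = 0.0636 with an estimated correlation). Anthocyanin genes fell in 8 of 9 cases (9 over the list alone), with chalcone synthase CHS at log2 -2.28 and LDOX at -2.00 (camera adjusted p = 7.5e-05, and adjusted p = 0.0636 with an estimated correlation). Photosynthesis genes rose in 5 of 10 cases, as over the list alone, with CAB2 at log2 1.42 (camera adjusted p = 0.0037, and adjusted p = 0.278 with an estimated correlation). In the transposon-related class 7 of 74 rose and 17 fell (7 and 15 over the list alone), with a mean of 0.13 while camera pointed down (adjusted p = 0.19). Of 24429 genes 10415 were called, 5196 higher and 5219 lower, and 2634 changed at least 2-fold (1749 higher, 885 lower).

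The SAM comparison asked the same in dividing tissue. PERK13, a receptor kinase gene known from root hairs, rose by log2 6.28, VIM4 by 5.97, TIL2 by 5.76, the glutamate receptor gene ATGLR1.2 by 5.29, SDH1-2 by 5.22 and AtSPO22 by 4.71. QQS was listed at 0 in tcx5/6 and at 3196 and 3022 in WT. The other genes named for large falls were PPME1, VGDH2, VGD1, PGA4 and HA6, each known from pollen, and pollen genes were not tested as a group. PPME1, a pectin methylesterase gene, was listed at 0 in tcx5/6 and at 698.9 and 479.2 in WT, and VGDH2 (log2 -8.87), VGD1 (-7.86), the polygalacturonase gene PGA4 (-6.56) and the proton pump gene HA6 (-8.05) fell. The pollen coat gene GRP17 read 17330 and 15330 in WT SAM and 1964 and 1976 in tcx5/6 SAM, so transcripts known from flowers were present in the SAM libraries. These transcripts differed between the genotypes, and a different stage or share of flower tissue was not tested. Any SAM change, and any difference between SAM and leaf, may carry this too.

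Meiosis genes rose in 12 of 14 cases in SAM (13 over the list alone, camera adjusted p = 4.6e-09), with ASY1 at log2 3.86. DNA damage genes rose in 11 of 12 cases, as over the list alone (camera adjusted p = 3.2e-06), with NAC044 at log2 4.42. Salicylic acid defence genes rose in 12 of 13 cases, as over the list alone (camera adjusted p = 1.1e-10), with PR2 at log2 2.39. Replication genes rose in 21 of 27 cases (24 over the list alone), with ORC1B at log2 1.36 (camera adjusted p = 1.5e-09, and adjusted p = 0.116 with an estimated correlation). In methylation maintenance 9 of 12 rose, as over the list alone, with CMT3 at log2 1.64 (camera adjusted p = 4.8e-07, and adjusted p = 0.0867 with an estimated correlation). DREAM subunits and E2F factors rose in 15 of 17 cases (16 over the list alone), with ALY1 at log2 2.80 (camera adjusted p = 1.7e-09, and adjusted p = 0.0867 with an estimated correlation). Photosynthesis genes fell in 10 of 10 cases, as over the list alone, with RBCS1B at log2 -1.35 (camera adjusted p = 4.6e-09, and adjusted p = 0.0867 with an estimated correlation). Floral organ genes fell in 3 of 9 cases, as over the list alone, with SEP2 at log2 -1.53 (camera adjusted p = 0.073). The stem cell regulator WUS fell by 1.65 on the log2 scale. In the transposon-related class 10 of 74 rose and 8 fell (9 and 7 over the list alone), with a median of 0.05 and a mean of -0.03 (camera adjusted p = 0.66). Of 24429 genes 7356 were called, 3815 higher and 3541 lower, with 2439 at least 2-fold (1209 higher, 1230 lower). Leaving out WT replicate 1 or 2 left 4675 or 4751.

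**Figure D5:**
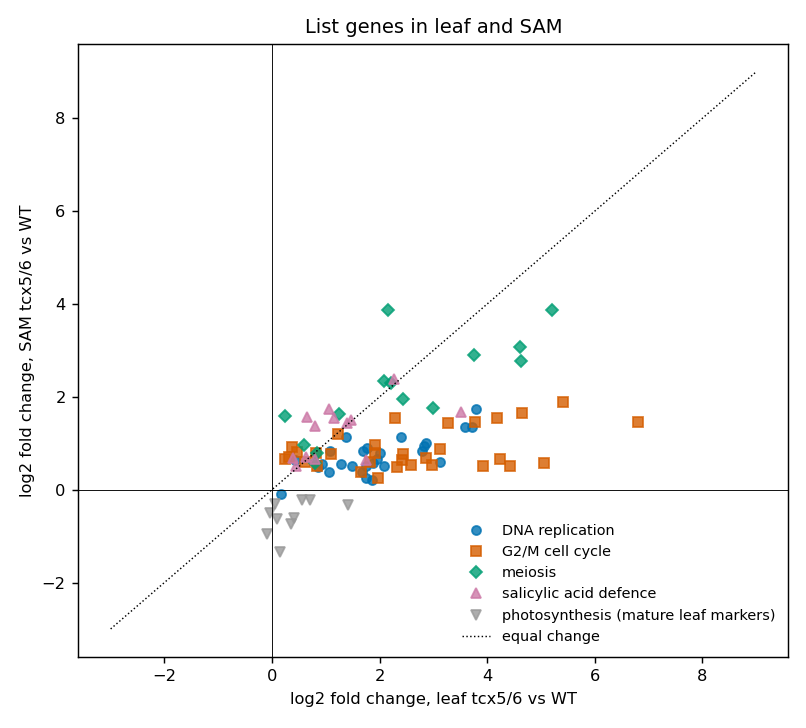
Log2 change of tcx5/6 against WT in leaf (horizontal axis) and SAM (vertical axis) for members of 5 gene lists, with a point for each gene and a dotted line of equal change. The median of the DNA replication list was 1.76 in leaf and 0.64 in SAM.

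Genes called in the same direction were shared between tissues and backgrounds more often than expected. Of the 1816 genes higher in tcx5/6 seedlings, 1220 were also higher in tcx5/6 ddm1 against ddm1, where 321 were expected (odds ratio 12.8), and of the 1089 lower genes 713 were also lower, where 235 were expected (7.77). Higher genes of seedlings and leaf shared 1158 (400 expected), those of seedlings and SAM 1277 (294 expected) and those of leaf and SAM 2140 (811 expected). Lower genes shared 559 (240 expected), 705 (149 expected) and 1288 (756 expected) in the same order. The highest p of the 8 Fisher's exact tests was 2.6e-105, and genes are not independent replicates. Comparisons from the same table also share the variance estimate of each gene, so their calls are linked even without a shared library. In all 4 comparisons 810 genes were higher and 308 lower, of 23277 tested in each. Of the 198 list tests 94 passed camera at the preset correlation, and 12 also passed with an estimated correlation. With fry 134 passed, 87 of them also called at the preset correlation in the same direction. The 12 were the TCX family, DREAM and E2F, methylation maintenance, replication, DNA damage and meiosis lists in tcx5/6 seedlings (adjusted p = 0.0423, 0.0499, 0.0214, 0.0423, 0.0214 and 0.0423), the G2/M, meiosis and salicylic acid lists in leaf (0.0359, 0.036 and 0.0359) and the DNA damage, meiosis and salicylic acid lists in SAM (0.0497, 0.032 and 0.032). The TCX family list holds TCX5 and TCX6 themselves.

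WT SAM against WT leaf described the tissues. The meristem regulator STM was listed at 0 in leaf and at 1587 and 1510 in SAM, and all 32 G2/M genes were higher in SAM, as over the list alone, with CYCB1;2 at log2 8.31 (camera adjusted p = 1.3e-08, and adjusted p = 0.0621 with an estimated correlation). GER3 (log2 13.90) and the epidermal gene PDF1 (13.27) were among the largest rises, and GRP17 was listed at 0 in leaf. KTI1 was listed at 0 in SAM and at 6028 and 5774 in leaf, IMS2 at 0 and at 3785 and 3585, and AACT1 was lower in SAM by log2 -12.02. Shoot meristem markers were higher in 11 of 12 cases and floral organ markers in 9 of 9, as over the lists alone (camera adjusted p = 0.0024 and 0.0003), with adjusted p = 0.135 and adjusted p = 0.106 with an estimated correlation. Photosynthesis genes, listed as leaf markers, were higher in SAM in 9 of 10 cases, as over the list alone, with RBCS1A at 426600 ± 1090 against 129500 ± 2790 (camera adjusted p = 0.0024, and adjusted p = 0.214 with an estimated correlation). Salicylic acid defence genes were lower in SAM in 12 of 13 cases, as over the list alone, with PR2 at 502.6 ± 25 against 66790 ± 579 (camera adjusted p = 2.3e-06, and adjusted p = 0.0621 with an estimated correlation). Transposon-related genes were higher in 40 of 74 cases and lower in 8, as over the list alone (camera adjusted p = 0.016, and adjusted p = 0.157 with an estimated correlation). The members with the smallest p-values were ADC1 (log2 -1.65), which encodes an arginine decarboxylase, DAYSLEEPER (2.06), a domesticated transposase, and AT3G19120 (1.55), so the class holds host genes. Of 24429 genes 19260 were called, 10561 higher and 8699 lower in SAM.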

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

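The tests of explanations in this part were chosen after the results were seen, except the test of time of day. The 2 interactions were planned before the data were examined.

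The tcx5/6 difference was not the same in plants labelled ddm1 as in plants not labelled ddm1. DDM1 signal in tcx5/6 ddm1 was near that of WT (611.6 ± 60.6 and 678.6 ± 43.4) and above that of ddm1 (132 ± 18.7), so the 2 ddm1-labelled groups differed in DDM1 transcript too. QQS was listed at 0 in both tcx5/6 seedling libraries and at 1021 and 1031 in WT, but read 2246 and 1991 in tcx5/6 ddm1 and 1826 and 1851 in ddm1 (fitted interaction 10.21, a size that depends on the pseudocount). The iron-response regulator BHLH100 was lower in tcx5/6 (33.97 ± 1.37 against 389.7 ± 129) and higher in tcx5/6 ddm1 (1241 ± 0.193 against 164.6 ± 10.3), an interaction of log2 6.35. MRU1 had an interaction of 5.90, the light-signalling gene PAR1 -4.62, the marneral synthase gene MRN1 -4.52 and the microRNA locus MIR399d -5.12. Smaller differences were found in the ribonucleotide reductase gene TSO2 (1.69), VIM3 (0.92), CDKB1;1 (0.87), PRD3 (0.85), HTA7 (0.59), the antenna gene LHCB2.1 (-0.98), the root gene PRP3 (-2.02), LUX (-1.05) and CHS (1.23). What marked each of these was a test of the difference between backgrounds, which called 3632 of 25016 genes. Of 27 replication genes 11 had a larger tcx5/6 difference in plants labelled ddm1 and 16 did not pass (15 over the list alone, camera adjusted p = 7.6e-09, and adjusted p = 0.361 with an estimated correlation). Without WT replicate 1 or 2 or tcx5/6 replicate 1 or 2 the count was 1410, 1534, 1559 or 1280. MIR399d lost its call without tcx5/6 replicate 1 (adjusted p = 0.061), CDKB1;1 without WT replicate 1 or tcx5/6 replicate 2 (0.056 and 0.066) and HTA7 without WT replicate 1 or tcx5/6 replicate 1 (0.075 and 0.071). PRD3 lost it without WT replicate 1 or 2 or tcx5/6 replicate 1 or 2 (0.057, 0.06, 0.053 and 0.085), and LHCB2.1 without WT replicate 1 or 2 or tcx5/6 replicate 2 (0.073, 0.059 and 0.08). The interaction sets libraries of 2 kinds against each other. Most replication genes also read lower in ddm1 than in WT, and whether this lower starting level gave the larger folds was not tested. Of the 3 with the smallest p-values, TSO2 and PCNA1 read higher in tcx5/6 ddm1 than in tcx5/6 (13090 against 5821 and 1008 against 888.3). MCM3 read lower (1339 against 1626).

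The tcx5/6 difference also varied between SAM and leaf, by a test of the difference between tissues that called 7501 of 24429 genes. ESM1 fell less in SAM than in leaf (interaction log2 4.09), from 78880 ± 860 to 11700 ± 172 against 24830 ± 3.89 to 215.3 ± 8.14. The tcx5/6 change was also higher in SAM than in leaf for the transporter gene DTX1 (3.84), the wax synthesis gene KCS19 (3.42), NRPD2 (1.00) and the anthocyanin regulator MYB90 (2.52). CSLA01 (-5.71), VGD1 (-5.57), SPP1 (-5.55), VIM3 (-3.06), TSO2 (-2.52), the checkpoint gene MAD2 (-3.41), HTR13 (-2.33), RBCS1A (-1.10) and SEP1 (-3.24) went the other way. KCS19 and VGD1 lost their calls with a pseudocount of 0.1 (adjusted p = 0.06 and 0.083). Of 27 replication genes 19 had a smaller difference in SAM and 8 did not pass (23 over the list alone, camera adjusted p = 1.4e-10, and adjusted p = 0.158 with an estimated correlation). For all 10 photosynthesis genes the tcx5/6 change was lower in SAM than in leaf, as over the list alone (camera adjusted p = 6.1e-10, and adjusted p = 0.158 with an estimated correlation). For 7 of 9 anthocyanin genes the tcx5/6 change was higher in SAM than in leaf, as over the list alone (camera adjusted p = 7.1e-05, and adjusted p = 0.122 with an estimated correlation). Without SAM WT replicate 1 or 2 the count of called genes was 4738 or 4983.

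TCX6 read 3.03 to 5.11 times higher in the lowest library labelled tcx5/6 than in the highest matching library, in each of 4 pairs of groups. An exchange of labels between single libraries would bring that ratio below 1, and the lowest was 3.03. Reads of TCX5 counted under TCX6 are also argued against, since the gain of TCX6 exceeded the loss of TCX5 in every pair (lowest ratio 1.28). Release of TCX6 from repression by its own complex stays open. Its log2 change was 0.52 below the largest of the DREAM list (difference -0.52), and without values per exon a truncated transcript could not be looked for.

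Clock genes stood apart in ddm1 and tcx5/6 ddm1 seedlings. A trend on gene length and signal level is argued against as the whole cause. It spanned only 0.27 over bins of signal level in ddm1, where dawn and dusk clock genes differed by -6.95. Its removal kept 101% of that difference. Other effects of the library kind could not be tested this way. The 8 dawn and 6 dusk output genes outside the clock list differed by -8.37 in ddm1 and -8.51 in tcx5/6 ddm1, and by -0.49 in tcx5/6. That was predicted for harvest at another time of day. Output genes follow the clock whatever moves it, so the test cannot single out this cause. Harvest at another time of day stays open. Loss of DDM1 function cannot be told apart from it, since 0 ddm1 libraries had an even-step share within the range of the WT and tcx5/6 seedling libraries. Any seedling comparison of those libraries with WT carries this difference too.

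Of 27 replication genes 19 rose by larger folds in leaf than in SAM and 8 did not pass the test of the difference, among them LIG1, with log2 0.43 in leaf and 0.64 in SAM. Meristem tissue carried into leaf samples labelled tcx5/6 is argued against, since 9 meristem markers gained at most 0.75% of their WT SAM level in leaf, against a lower quartile of 17.8% and a median of 29.7% for replication genes. A low starting level in leaf could give larger folds from similar gains, and 18 of 27 replication genes gained at least as much signal in SAM as in leaf (binomial p = 0.12), which leaves it open. A difference between the tissues in how TCX5 and TCX6 act stays open as untested.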

How the results depend on the processing

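The filter at a value of at least 20 was chosen after seeing the data and the other alternatives before. Each group had 2 libraries, so a lone library left after leaving out its partner was assumed to vary like the other groups. TMM or RLE of edgeR, filterByExpr, edgeR quasi-likelihood fits and DESeq2 were not run because the values are not counts, and for the interactions a fit on the compared groups alone is the fit on all groups itself.

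With an absolute log2 change of at least 1 the counts were 943 (tcx5/6 against WT seedlings), 5376 (ddm1 against WT), 6650 (tcx5/6 ddm1 against WT), 3513 (tcx5/6 ddm1 against ddm1), 1658 (seedling interaction), 2634 (leaf), 2439 (SAM), 2390 (tissue interaction) and 12715 (WT SAM against WT leaf), fewer because a threshold was added. A fit on the compared groups alone called 6508 for tcx5/6 against WT seedlings, where the main fit called 2905. It called 6497 for tcx5/6 ddm1 against ddm1, where the main fit called 9832. The SD of log2 differences between replicates was 0.166 in WT and 0.165 in tcx5/6 seedlings. It was 0.313 in ddm1 and 0.291 in tcx5/6 ddm1. The main fit shares 1 variance per gene over all groups, which can be too large for the first pair and too small for the second. Calls of the second pair may therefore be too many, and the cause was not tested further. Leaving out 1 library at a time, which leaves fewer samples, gave ranges of 988 to 1313 for tcx5/6 against WT seedlings, 1280 to 4121 for the seedling interaction, 4675 to 5068 for SAM and 4738 to 8750 for the tissue interaction. The other counts stayed within 1.5 times, at 9057 to 11311 (ddm1), 10916 to 13305 (tcx5/6 ddm1 against WT), 7793 to 9083 (tcx5/6 ddm1 against ddm1), 7999 to 10560 (leaf) and 17642 to 17993 (WT SAM against WT leaf). With an estimated correlation 12 of 94 list calls remained, and the cause was not tested.

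Rescaling by the median of ratios, no low-value filter, a pseudocount of 0.1, the replicate number as a block and the filter at 20 left every count within 1.5 times, with 2982, 2867, 2784, 2810 and 3170 for tcx5/6 against WT seedlings. Rescaling shifted the median log2 change by at most 0.0572. SDC reversed in the seedling interaction with a pseudocount of 0.1, at 0.50 against -2.52, where it did not pass (adjusted p = 0.64), because tcx5/6 was listed at 0. Correlations of deviations between replicates of the same number lay between -0.046 and 0.1 in seedlings and between -0.081 and 0.022 in leaf and SAM. Of named genes, 10 lost their call with a pseudocount of 0.1, 5 with a block and 13 with a fit on the compared groups alone. In the leave-one-out fits 2696 of 2987 results kept direction and side of the threshold.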

Other observations

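The test of the hypothesis in this part was chosen after its pattern was seen.

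The values of some genes in each seedling library were as follows. ESM1 read 20510 and 20100 in WT, 1064 and 1076 in tcx5/6, 115400 and 104000 in ddm1, and 104700 and 77820 in tcx5/6 ddm1. MRU1 read 229.2 and 199.7, then 1.408 and 1.552, then 5395 and 5416, then 4261 and 3266 in the same order. The iron-response regulator bHLH39 read 360.9 and 260.9 in WT, 40.66 and 58.07 in tcx5/6, 157.7 and 162.5 in ddm1, and 1257 and 1153 in tcx5/6 ddm1. The iron transporter gene IRT1 read 113.2 and 164.4, 259.7 and 150.5, 218.5 and 174.5, and 689.7 and 1015. AT4G28870, a transposon-related gene, was listed at 0 in all seedling libraries except ddm1, at 82.92 and 82.47. FWA was listed at 0 in WT and tcx5/6, and read 19.17 and 369 in the 2 tcx5/6 ddm1 libraries, which differed more than the 147.8 and 252.2 of ddm1.

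MAP1B and QQS were lower in tcx5/6 in seedlings, leaf and SAM. MAP1B read 130.9 ± 10.1 against 579.2 ± 12 in seedlings, 228.6 ± 41.6 against 1245 ± 3.08 in leaf and 32.06 ± 6.91 against 304.1 ± 11.6 in SAM.

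Genes lower in tcx5/6 may include some that gain signal in ddm1. Among 147 genes at least 2-fold lower in both leaf and SAM, 47 were called higher and 33 lower in ddm1 seedlings, against 515 higher and 518 lower of 2359 genes with a similar WT signal (odds ratio of being higher 1.68, Fisher's p = 0.0058). Among genes higher by at least 2-fold in both tissues the odds ratio was 1.05 (Fisher's p = 0.62), but 257 of those 618 genes were called lower in ddm1, against 1601 of 7674 with a similar WT signal, a difference that was not tested. The ddm1 libraries were of another kind than WT, so part of this difference may come from the kind. Some of the 147 genes were near the floor in leaf, such as the pollen gene VGD1 (4.3 ± 2.87 in WT and 0 in tcx5/6). Fisher's exact test also treats genes as independent, which they are not.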
